A study of Danio rerio with 72 samples.

How the data were processed

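Amplicon sequencing of a genomic barcode was analysed in 72 single zebrafish embryos, 1 library per embryo. Per the labels' protocols, embryos were grown at 28.5 °C for 2 days, SpyCas9 was induced by heat shock at 37 °C for 30 minutes (a statement that stands in the labels of all groups, so whether embryos without SpyCas9 were heat-shocked is not clear), genomic DNA was prepared by HotSHOT lysis, and libraries were made by 2 rounds of PCR that added adapters and dual indexes of 8 bp. Trimmomatic was used, per the submitters' processing notes; its version, the aligner, the edit caller, the barcode reference and the genomic location of the barcode are not given in the sources used here. Groups were taken from the labels: 14 unedited, 8 LbaCas12a, 8 SauCas9, 7 SpyCas9 and 35 triple embryos.

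The deposited file of each embryo lists barcode alleles, each as a string of calls at 15 target sites, with the count of reads per allele, per the file headers. The authors also deposited each allele as a proportion, a fraction of the embryo's reads; it differed from count over total by at most 1.11e-16 and was used for this check only. No other normalization of the deposited counts was found, and 0 calls were undetermined. Embryos had 19496 to 157330 reads, and alleles of a single read held 3.34% to 27.4% of an embryo's reads.

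An edit was 1 event (deletion, insertion or substitution) with its length, its start as numbered in the calls and any inserted bases; a deletion over several sites counted at each. All alleles entered the main values. Measures per embryo were the share of reads with any edit, the share edited at each site, and the share edited at 1 or more of a nuclease's sites. Further measures were the share with an edit at another nuclease's sites that touched no site of the embryo's own nuclease, the share of edited reads with a deletion over 2 or more sites, and, at own sites, the insertion share of edits by reads and the median deletion length by reads. Distinct edited alleles were rarefied to 19496 reads by the hypergeometric formula. A site was assigned to the nuclease whose single-nuclease embryos had the highest mean there, if they passed against unedited embryos; triple embryos were not used for this.

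Groups were compared by two-sided exact permutation tests of the rank sum (midranks, full distribution) with the embryo as replicate. P-values were adjusted by Benjamini-Hochberg within each family: 4 comparisons for edited reads against unedited, 6 between edited groups, 60 for sites, 6 for edits at other nucleases' sites, 3 for triple against single nuclease, 10 for distinct alleles, 6 for multi-site deletions and 3 for each measure of edit type and size. The threshold was an adjusted p of 0.05. On simulated values this test gave 4.80% false positives and found 98.4% of shifts of 2 SD with 8 against 14 embryos. Comparisons with unedited embryos share those embryos and their chance values.

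Counts of reads per edit were compared with unedited embryos by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with all reads of the embryo as library size and no TMM scaling, for edits with at least 10 reads in at least 3 embryos. The edits named are, for each edited group, the 6 with the highest mean read share among those called higher than unedited and present at 10 or more reads in at least 50% of the group's embryos. The test was run on simulated counts with 200 changed edits. Wrong calls were 7.14% of calls for LbaCas12a, 5.65% for SauCas9, 4.76% for SpyCas9 and 63.8% for triple embryos, and other edgeR settings tried on the simulated triple counts did not mend this. With edits of at least 10 reads in at least 50% of triple embryos, 1.04% of calls were wrong, so the triple result leads with those. There 200 of 1100 edits were changed, against 200 of 5985 among all tested triple edits. The share of wrong calls depends on the share of changed edits, so 1.04% and 63.8% are not directly comparable. Neither gives the share of wrong calls in the real counts. The edits in at least 50% of triple embryos were chosen on the real counts before simulation, so their rate leaves out any effect of that selection.

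The measures, tests, naming rule and most alternatives were chosen before the data were examined. These alternatives were: leaving out alleles of fewer than 5 reads or under 0.1% of reads, leaving out edits of 1 bp, a test on the difference of means with 100000 resamples, and a replicate block. Single-site edits only, no rarefaction, alleles of at least 0.1% of reads, the effective number of alleles, each allele counted once, deletions over 3 or more sites and all edits of the embryo were the others for single measures. For edits they were DESeq2 1.42.0, the rank-sum test on read shares, TMM scaling, no filter and a minimum of 50 reads. Chosen after seeing the data were leaving out substitution calls, leaving out each embryo in turn, using unedited embryos of the same library set, doing so without substitution calls (for edits at other nucleases' sites), counting agreeing unedited embryos once, counting only edits confined to a nuclease's own sites, and the restriction to edits in at least 50% of a group's embryos. Library sets were defined by substitution calls at position 49, with a cutoff of 2 per 10000 reads. Bootstrap intervals (95%) used 1000 resamples of embryos and were chosen after seeing the data. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. No embryo was left out. No edit was placed in the genome.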

Results

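The series measured editing of a genomic barcode in single zebrafish embryos by amplicon sequencing. A recording barcode of this kind is a stretch of DNA with consecutive nuclease target sites, in which each insertion or deletion left by repair is inherited by the daughters of the edited cell. The deposited calls listed 15 target sites per barcode. The 72 embryos were of the TU wild-type background, were grown at 28.5 °C and were collected at 2 days post fertilization. They fell into 5 groups by the nucleases used: 14 unedited embryos, 8 edited with LbaCas12a, 8 with SauCas9, 7 with SpyCas9 and 35 with all 3 nucleases (triple embryos). SpyCas9 and SauCas9 are Cas9 nucleases of different bacteria, each recognising its own guide RNA and its own PAM (the short motif beside a target). LbaCas12a belongs to another nuclease family that recognises a T-rich PAM and leaves staggered ends. Where the barcode lies in the genome, and its reference sequence, are not given in the sources used here, so sites are numbered by their order in the calls and edits by the positions in the calls.

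The files held 5349087 reads in all, spread over 894160 alleles counted within embryos, where an allele is one combination of edits over the 15 sites. Reads per embryo ranged from 19496 to 157330. The median was 54632 in unedited, 100155 in LbaCas12a, 80083 in SauCas9, 99704 in SpyCas9 and 72908 in triple embryos. Deletions were 85.1% of the called events by reads, insertions 10.8% and substitutions 4.13%. The reads carried no molecular identifiers, so counting intervals cover counting error only; the widest 95% Wilson interval of an embryo's edited read share was ± 0.387 percentage points. Each embryo was 1 replicate. Whether embryos shared parents is not given in the sources used here.

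Nearly every read of triple embryos was edited. The share of reads with an edit at 1 or more sites was 99.8% ± 0.432 (SD, n = 35) in triple embryos, 86.3% ± 18.5 (n = 8) with LbaCas12a, 83.5% ± 12.7 (n = 8) with SauCas9 and 41.4% ± 16.2 (n = 7) with SpyCas9. Unedited embryos gave 5.20% ± 0.637 (n = 14), the background of the same measure. All 8 LbaCas12a, 8 SauCas9, 7 SpyCas9 and 35 triple embryos lay above all unedited embryos, with adjusted p = 8.34e-06, 8.34e-06, 1.72e-05 and 1.18e-11 (two-sided exact rank-sum permutation tests, Benjamini-Hochberg over 4 comparisons).

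LbaCas12a and SauCas9 each edited a larger share of reads than SpyCas9, by 44.9 and 42.1 percentage points (adjusted p = 0.00149 for both, exact rank-sum permutation test over 6 pairs of groups). Of the 8 LbaCas12a embryos 6 lay above all SpyCas9 embryos, as did 6 of the 8 SauCas9 embryos. LbaCas12a and SauCas9 were not separated (difference 2.82 percentage points, adjusted p = 0.574). Triple embryos exceeded every single-nuclease group: the difference from them was -13.4 percentage points for LbaCas12a (adjusted p = 0.000351, 5 of 8 embryos below all triple embryos), -16.2 for SauCas9 (adjusted p = 0.000108, 6 of 8) and -58.3 for SpyCas9 (adjusted p = 4.45e-07, 7 of 7) in the same exact tests. The LbaCas12a value rested partly on replicate 2, in which 47.9% of reads were edited: without it the difference of LbaCas12a from triple embryos was -7.92 percentage points.

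The libraries fell into sets by substitution calls at barcode position 49, beside site 1. Such calls occurred in at least 2 per 10000 reads in a first set of libraries and in fewer in a second set. The first set held 9 unedited embryos, all embryos of the single-nuclease groups and 1 triple embryo; the second held 5 unedited and 34 triple embryos. Edited reads were 5.62% ± 0.336 in the 9 unedited embryos of the first set and 4.45% ± 0.0399 in the 5 of the second (exact rank-sum permutation p = 0.000999). Counting once those unedited embryos that differed by less than sampling noise leaves 7 and 2 values, with p = 0.0556, the smallest that such an exact test can give. Against unedited embryos of the same set, edited read shares were higher by 80.7 percentage points with LbaCas12a, 77.9 with SauCas9, 35.8 with SpyCas9 and 95.3 in triple embryos. Any difference between triple and single-nuclease embryos coincides with the library set, and 1 triple embryo in the first set is too few for a comparison within it.

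Some unedited embryos resembled each other closely. Of 91 pairs of unedited embryos, 9 differed by less than sampling noise in a chi-square test of their edits, namely those among replicates 2, 4 and 6 and among replicates 11 to 14. They were kept as separate embryos, as the labels list them; whether any was measured more than once was not settled. Counting each set once leaves 9 unedited values, and the edited read shares were then higher by 80.9, 78.1, 36.0 and 94.4 percentage points in the order above.

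Which nuclease edits which site was read from the single-nuclease embryos, since the labels do not pair them, so the tests of single-nuclease embryos at their own sites are no independent evidence of the pairing. Sites 1 to 5 were edited most by LbaCas12a, sites 6 to 10 by SauCas9 and sites 11 to 15 by SpyCas9. In LbaCas12a embryos the mean share of reads edited at sites 1 to 5 was 59.5%, 51.9%, 73.4%, 53.1% and 59.5%, with SDs of 25.1 to 30.7 (n = 8). In SauCas9 embryos sites 6 to 10 reached 33.1%, 39.8%, 63.4%, 49.5% and 46.3%, with SDs of 16.3 to 22.2 (n = 8). In SpyCas9 embryos sites 11 to 15 reached 23.8%, 34.0%, 34.4%, 29.1% and 30.7%, with SDs of 14.7 to 17.3 (n = 7). Unedited embryos had 0.228% to 1.14% at each of the 15 sites.

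All 15 sites were edited in triple embryos. Sites 1 to 5 reached 53.3%, 40.7%, 73.5%, 54.5% and 73.6%, sites 6 to 10 reached 41.5%, 45.3%, 53.7%, 36.7% and 42.2%, and sites 11 to 15 reached 70.8%, 77.2%, 77.0%, 58.0% and 67.8%, with SDs of 9.91 to 20.4 (n = 35). Every triple embryo exceeded every unedited embryo at each site (adjusted p = 1.18e-11, exact rank-sum permutation test, Benjamini-Hochberg over 60 comparisons). A deletion over several sites counts at each of them. With edits that touch a single site only, the differences from unedited at sites 11 to 15 in SpyCas9 embryos were 5.09, 4.72, 1.41, 0.410 and 3.13 percentage points, and those at sites 6 to 10 in SauCas9 embryos 21.0, 13.0, 29.1, 15.6 and 23.6; all passed the exact test.

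**Figure D1:**
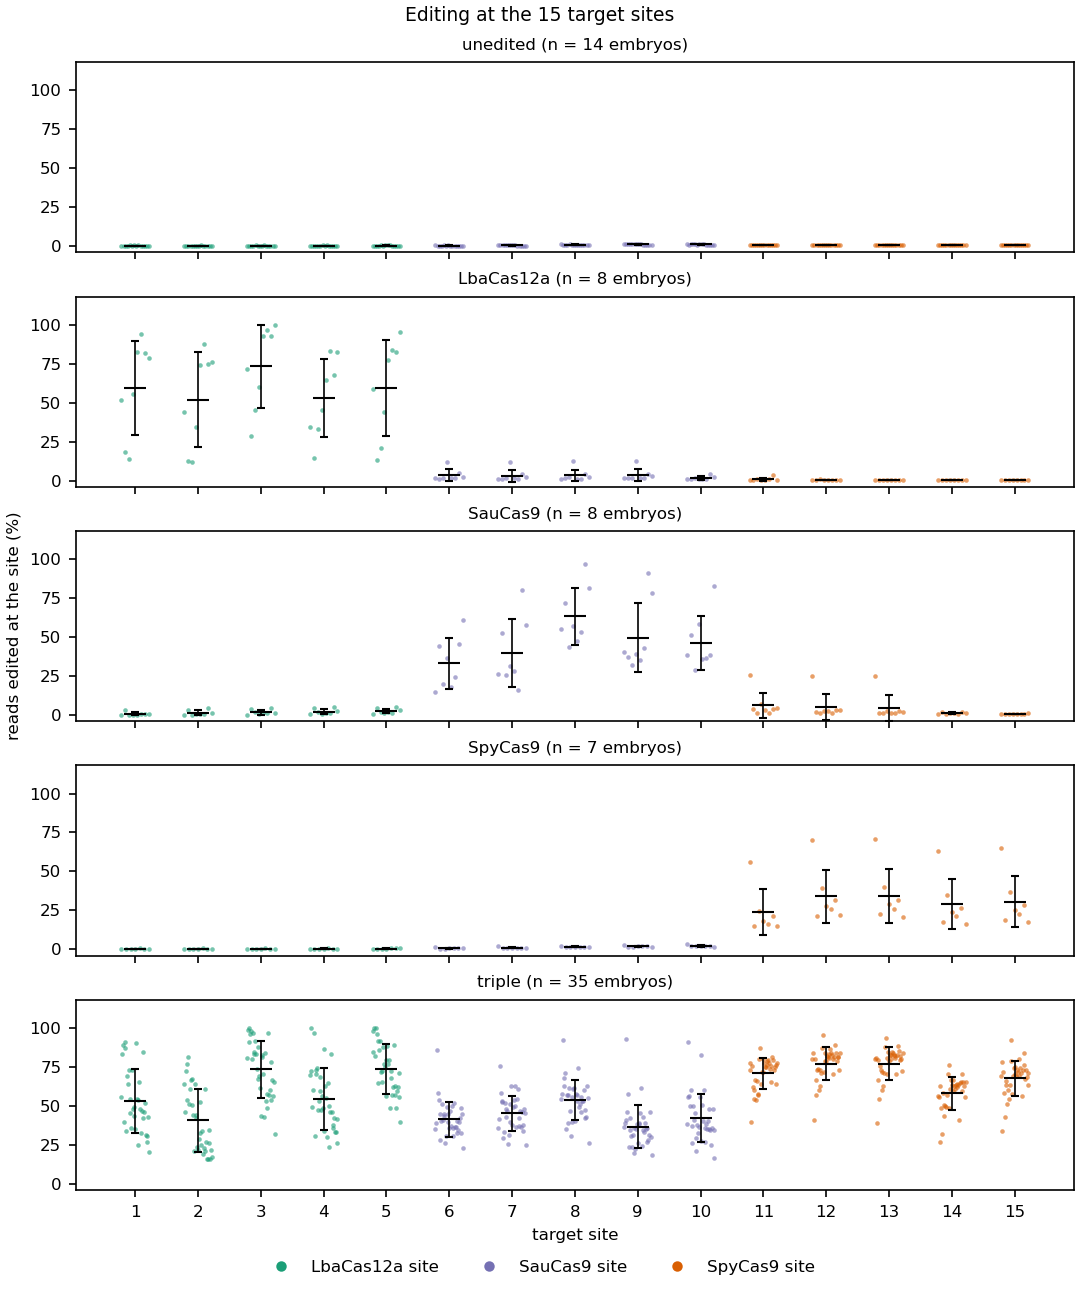
Share of reads edited (percent) at each of the 15 target sites, 1 panel per group. Points are embryos coloured by the nuclease to which the site was assigned, bars are mean ± SD; single-nuclease embryos sit high at 5 sites each and triple embryos at all 15.

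Edits also appeared at sites outside a nuclease's own 5. LbaCas12a embryos were above unedited at sites 6 to 9, with means of 3.41%, 3.09%, 3.26% and 3.35% against 0.308%, 0.524%, 0.842% and 1.14% (adjusted p = 1.10e-05, exact permutation). SauCas9 embryos were above unedited at sites 2 to 5 and 11 to 14, the highest being 6.26% ± 7.92 at site 11 (n = 8). SpyCas9 embryos were above unedited at sites 5 to 10, the highest being 2.13% ± 0.650 at site 10 (n = 7); without alleles under 0.1% of reads they were above at their own 5 sites only. Against unedited embryos of the first library set alone, SpyCas9 embryos no longer passed at site 5 (difference 0.157 percentage points), nor SauCas9 embryos at site 2 (1.03). LbaCas12a embryos were below unedited at sites 12 to 15, with 0.485% to 0.570% against 0.608% to 0.768%; 2 of these 4 sites stayed below without alleles of fewer than 5 reads, and 0 without alleles under 0.1% of reads.

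Part of this lay in deletions over several sites. Counting only edits that touch a single site, LbaCas12a embryos were above unedited at 7 sites instead of 9 and SauCas9 embryos at 6 instead of 13. SauCas9 embryos were then below unedited at sites 12 to 15, and SpyCas9 embryos were above at 9 sites instead of 11. Single embryos carried part of the means. Without LbaCas12a replicate 4 the differences at sites 6 to 9 were 1.86, 1.29, 1.12 and 0.927 percentage points, against 3.11, 2.57, 2.41 and 2.21 with it. Without SauCas9 replicate 1 those at sites 11 to 13 were 2.77, 1.56 and 1.03, against 5.50, 4.41 and 3.95, and without SauCas9 replicate 7 that at site 2 was 0.623, against 1.09. LbaCas12a embryos, not separated from unedited at site 11 (difference 0.195), were below unedited there without replicate 7 (-0.145). SpyCas9 embryos, not separated at site 4 (difference 0.137), were above unedited there without SpyCas9 replicate 2 (0.171) or unedited replicate 7 (0.154) or 9 (0.158).

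To ask whether the nucleases edit each other's sites, edits that touched any site of the embryo's own nuclease were set aside. What remained at the other nucleases' sites was small. It was 4.00% ± 0.434 of reads at SauCas9 sites in LbaCas12a embryos (n = 8) against 3.13% ± 0.588 in unedited embryos (n = 14), and 1.92% ± 1.49 at LbaCas12a sites in SauCas9 embryos against 0.738% ± 0.351. SpyCas9 embryos had 1.16% ± 0.279 at LbaCas12a sites (n = 7) against 0.741% ± 0.351 and 3.82% ± 0.265 at SauCas9 sites against 3.13% ± 0.589. These 4 were above unedited, with adjusted p = 0.000844, 0.000844, 0.0190 and 0.00243 (exact rank-sum permutation tests, Benjamini-Hochberg over 6 comparisons), and 5 of 8, 5 of 8, 2 of 7 and 4 of 7 embryos lay above all unedited embryos. At SpyCas9 sites LbaCas12a embryos were below unedited, 1.74% ± 0.139 against 2.13% ± 0.293 (adjusted p = 0.00120, exact test, 6 of 8 embryos below all unedited), and SauCas9 embryos, at 1.90% ± 0.367 (n = 8) against 2.13% ± 0.293, did not pass the test (adjusted p = 0.0594).

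Within the first library set the 5 differences that had passed were 0.456, 0.974, 0.212, 0.275 and -0.191 percentage points in the same order, and that of SpyCas9 embryos at LbaCas12a sites no longer passed the exact test. Without substitution calls the difference of LbaCas12a embryos at SauCas9 sites was 0.181 percentage points and that of SpyCas9 embryos at LbaCas12a sites 0.114, neither past the threshold. Within the first library set and without substitution calls, none of the 4 increases passed the exact test: the differences were 0.0990, 0.855, 0.0109 and 0.104 percentage points in the order above. The folds over unedited embryos of that set were then 1.12 (bootstrap interval 0.871 to 1.495), 2.82 (1.27 to 5.73), 1.02 (0.649 to 1.56) and 1.13 (1.00 to 1.26), against 1.13, 2.03, 1.22 and 1.08 with substitution calls. Without alleles under 0.1% of reads, only the difference of SauCas9 embryos at LbaCas12a sites still passed. The value of SauCas9 embryos at LbaCas12a sites rested partly on replicate 7, with a difference of 1.19 percentage points with it and 0.680 without it, and the comparison that had not passed, SauCas9 embryos at SpyCas9 sites, passed at -0.350 percentage points without SauCas9 replicate 4, at -0.236 without SauCas9 replicate 3 and at -0.252, -0.253, -0.251 and -0.253 without unedited replicates 2, 3, 4 and 8. Without alleles of fewer than 5 reads it passed in the other direction, at 0.294 percentage points.

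The triple embryos showed whether a nuclease edits as much beside the other 2 as it does alone. SpyCas9 sites were edited in 83.1% ± 9.44 of reads in triple embryos (n = 35) and in 39.2% ± 16.9 with SpyCas9 alone (n = 7), a difference of 44.0 percentage points, and 30 of the 35 triple embryos lay above every SpyCas9 embryo (adjusted p = 4.23e-06, exact rank-sum permutation test over 3 comparisons). LbaCas12a sites reached 92.8% ± 9.61 in triple embryos and 85.7% ± 19.3 with LbaCas12a alone (adjusted p = 0.678, exact test, n = 35 and 8). SauCas9 sites reached 81.9% ± 11.1 and 83.2% ± 12.9 (adjusted p = 0.939, exact test, n = 35 and 8). Counting only edits confined to a nuclease's own sites, the differences between triple and single-nuclease embryos were 41.5 percentage points for SpyCas9, 1.05 for LbaCas12a and -12.9 for SauCas9, and only that for SpyCas9 passed the exact test. All SpyCas9 embryos were in the first library set and 34 of the 35 triple embryos in the second, so nuclease combination and library set cannot be told apart here.

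**Figure D2:**
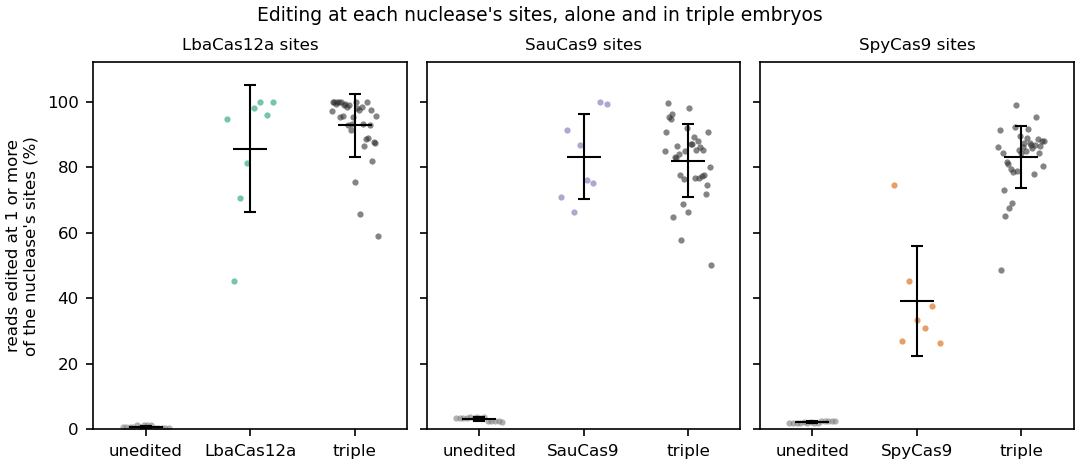
Share of reads (percent) edited at 1 or more of the 5 sites of LbaCas12a, SauCas9 and SpyCas9, in unedited embryos, embryos with that nuclease alone and triple embryos. Points are embryos and bars mean ± SD; the triple mean is 83.1% at SpyCas9 sites against 39.2% with SpyCas9 alone.

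Triple embryos held the most distinct barcodes. Rarefied to 19496 reads, the depth of the shallowest embryo, they had 7941 ± 1534 distinct edited alleles (n = 35), against 2885 ± 396 with LbaCas12a (n = 8), 3135 ± 673 with SauCas9 (n = 8) and 1989 ± 384 with SpyCas9 (n = 7). Unedited embryos had 943 ± 117 (n = 14), the number that background calls give. Triple embryos exceeded each single-nuclease group (adjusted p = 2.41e-07 for each, exact rank-sum permutation tests over 10 pairs), and 34, 34 and 35 of the 35 lay above all LbaCas12a, SauCas9 and SpyCas9 embryos. LbaCas12a and SauCas9 each exceeded SpyCas9 (adjusted p = 0.00155 and 0.00414, exact tests) and were not separated from each other (adjusted p = 0.798). Most of the alleles in triple embryos were rare: 57.2 ± 39.3 alleles per triple embryo reached 0.1% of reads, fewer than the 115 ± 23.2 with LbaCas12a and the 103 ± 23.0 with SauCas9, which turned both directions. With all alleles counted and no rarefaction, LbaCas12a embryos had 2720 more alleles than SauCas9 embryos, and SauCas9 and SpyCas9 were not separated. By the effective number of edited alleles (from the Shannon entropy) triple embryos again led with 6081 ± 2570, against 478 ± 220 with LbaCas12a, 639 ± 370 with SauCas9 and 247 ± 68.2 with SpyCas9, but unedited embryos had 2229 ± 582.

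Among edited reads, long deletions that remove several sites were most frequent where SpyCas9 was used. Only 41.4% of reads were edited with SpyCas9, against 83.5% with SauCas9. Over all reads the mean share with a deletion over several sites was higher with SauCas9 than with SpyCas9, which was not tested. A deletion over 2 or more sites was present in 95.4% ± 1.82 of edited reads in triple embryos (n = 35), 78.7% ± 7.58 with SpyCas9 (n = 7), 49.4% ± 16.6 with SauCas9 (n = 8) and 33.6% ± 23.8 with LbaCas12a (n = 8). All pairs of groups differed (adjusted p from 4.14e-08 to 0.00448, exact rank-sum permutation tests over 6 pairs) except LbaCas12a and SauCas9 (adjusted p = 0.279). In triple embryos 28.1% ± 8.37 of reads carried a deletion that joined sites of different nucleases, 62.7% ± 11.6 were edited at sites of all 3 nucleases, and 8.66 ± 0.984 of the 15 sites were edited per read (n = 35). With each allele counted once, LbaCas12a and SpyCas9 were no longer separated (difference -17.5 percentage points).

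**Figure D3:**
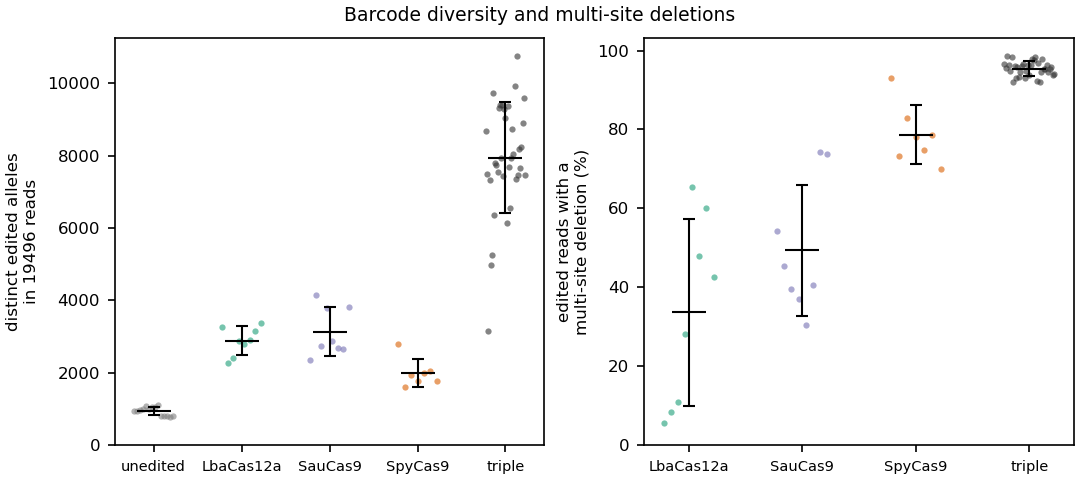
Left, distinct edited alleles per embryo after rarefaction to 19496 reads; right, percent of edited reads with a deletion over 2 or more target sites. Points are embryos, bars mean ± SD; triple embryos are highest in both, with means of 7941 alleles and 95.4%.

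The 3 nucleases left different edits at their own sites. The median deletion was 61.0 ± 11.8 bp with SpyCas9 (n = 7), against 12.1 ± 2.42 bp with LbaCas12a and 12.0 ± 5.78 bp with SauCas9 (n = 8 each), and every LbaCas12a and SauCas9 embryo lay below every SpyCas9 embryo (adjusted p = 0.000466 for both, exact rank-sum permutation tests over 3 pairs). Insertions were 16.8% ± 7.57 of edits with SauCas9, 9.07% ± 1.31 with SpyCas9 and 7.14% ± 6.03 with LbaCas12a. SauCas9 exceeded both LbaCas12a and SpyCas9 (adjusted p = 0.0210 for both, exact tests). The insertion shares of LbaCas12a and SpyCas9 differed by -1.93 percentage points (adjusted p = 0.0401, exact test), and by -3.94 without LbaCas12a replicate 1. It lay between -1.33 and -2.02, and no longer passed, when any 1 of LbaCas12a replicates 3 to 8 or of SpyCas9 replicates 2 and 4 to 7 was left out, and it did not pass without substitution calls, without edits of 1 bp or over all edits of the embryo. With each allele counted once, the LbaCas12a median deletion was 4 bp longer than that of SauCas9, and this difference passed the exact test.

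Many edits were called in embryo after embryo. Whether each arose separately in every such embryo was not tested. An edit is named by its length, its kind (D, deletion) and its start in the files' numbering, so that 13D+173 is a 13 bp deletion from position 173. Among edits with at least 10 reads in at least 50% of a group's embryos, edgeR's quasi-likelihood test, adjusted over all tested edits, called 427 of 460 more frequent than in unedited embryos with LbaCas12a, 430 of 445 with SauCas9, 310 of 340 with SpyCas9 and 1100 of 1100 in triple embryos. This selection by reads in the edited group favours edits that are higher there, so the shares called higher are partly fixed by it. Tested and adjusted on their own, such edits gave 430, 431, 310 and 1100 higher and 4, 1, 0 and 0 lower. Of those called first, 19 with LbaCas12a, 108 with SauCas9, 106 with SpyCas9 and 303 in triple embryos were over 2 or more sites. In triple embryos 1000 were deletions, 95 insertions and 5 substitutions, and 50 joined sites of different nucleases.

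The leading LbaCas12a edits were short deletions whose share varied widely between embryos. Deletion 13D+173 at site 5 took 9.53% ± 7.33 of reads (n = 8, log2 fold 9.86 over unedited), 17D+50 at site 1 took 8.20% ± 8.70 and 9D+116 at site 3 took 5.04% ± 12.6. Next came 18D+54, 9D+56 and 11D+54, all at site 1, with 4.38% ± 5.88, 3.92% ± 9.67 and 3.63% ± 9.05. Of these means 4 rested largely on 1 embryo each: 9D+116 took 36.3% of the reads of replicate 8 and a mean of 0.570% without it, 9D+56 took 27.8% in replicate 7 and 0.507% without it, 11D+54 took 26.0% in replicate 6 and 0.439% without it, and 18D+54 took 15.0% in replicate 4 and 2.86% without it. The leading SauCas9 edits were 5D+260 at site 8 with 8.43% ± 7.45 of reads (n = 8, log2 fold 12.05) and 5D+263 at the same site with 5.25% ± 2.71. They were followed by 4D+202, 4D+206 and 1D+205 at site 6 with 3.97% ± 2.38, 3.11% ± 2.92 and 2.92% ± 2.92, and by 6D+321 at site 10 with 2.91% ± 1.58. Adjusted p-values from edgeR's quasi-likelihood test lay between 7.43e-08 and 5.64e-05 for the LbaCas12a edits and between 1.48e-12 and 1.05e-10 for the SauCas9 edits.

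With SpyCas9 the leading edits were long deletions between its sites. Deletion 104D+348, from site 11 to site 15, took 8.56% ± 6.17 of reads (n = 7, log2 fold 9.25), 78D+375 from site 12 to site 15 took 6.68% ± 2.39, 52D+403 from site 13 to site 15 took 3.66% ± 1.48, and 51D+352 and 52D+351 from site 11 to site 13 took 2.30% ± 0.787 and 1.31% ± 0.255. Next was 6D+372 at site 12 with 0.767% ± 0.292. All 6 had at least 10 reads in all 7 SpyCas9 embryos, as did the 12 LbaCas12a and SauCas9 edits above in all 8 of theirs. In triple embryos 104D+348 led with 19.0% ± 5.26 of reads (n = 35, log2 fold 10.39), followed by 13D+173 with 8.85% ± 7.36, 51D+352 with 8.66% ± 2.00, 52D+403 with 8.25% ± 1.69, 17D+50 with 6.53% ± 7.43 and 78D+375 with 5.33% ± 1.69. Adjusted p-values of edgeR's quasi-likelihood test were at most 4.16e-15 for the SpyCas9 edits and at most 7.97e-12 for the triple edits. In unedited embryos these edits had a mean share of at most 0.0211% of reads (n = 14).

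Over all tested edits, those with at least 10 reads in at least 3 embryos, edgeR called 572 of 636 higher and 7 lower with LbaCas12a, 587 of 635 higher and 6 lower with SauCas9, and 431 of 492 higher and 0 lower with SpyCas9, where DESeq2 and the exact rank-sum test also called 0 lower and edgeR had 0 lower at an unadjusted p under 0.05. With TMM scaling it called 556 higher and 56 lower with LbaCas12a, 533 and 46 with SauCas9 and 382 and 46 with SpyCas9. In triple embryos edgeR without TMM scaling called 5913 of 5985 higher and 4 lower. In counts simulated for that comparison 229 of its 359 calls were wrong. Only 200 of the 5985 edits were changed in that simulation, and the share of wrong calls depends on how many edits differ. The simulated share therefore does not give the share of wrong calls among the real ones. The exact rank-sum permutation test on read shares called 4153 higher and 3 lower, and edgeR with TMM scaling 5038 higher and 70 lower.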

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

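All tests of explanations in this part were chosen only after the results were seen. Single embryos were far from the rest of their group by Dixon's test in 39 of 87 measures of the single-nuclease groups (13 LbaCas12a, 10 SauCas9 and 16 SpyCas9). Chance gives 5% for normally distributed values only, and many of these measures share reads. In all 39 the embryo was the highest of its group, and some measures were edits named for a high mean. The excess over 5% is therefore no evidence of unusual embryos. Counting intervals (95% Wilson) of these read shares were at most ± 0.308 percentage points.

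SpyCas9 replicate 1 stood above the other 6 SpyCas9 embryos in edited reads (75.4%), reads edited at its own sites (74.5%), sites 11 to 15 (56.3%, 69.9%, 70.9%, 62.8% and 65.2%), sites 7 to 10 (1.93%, 2.40%, 2.91% and 3.60%), rarefied edited alleles (2791) and the deletions 104D+348 (22.1%) and 51D+352 (4.00%). SpyCas9 replicate 5 stood apart at sites 4 and 5, with 0.762% and 1.02%.

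LbaCas12a replicate 4 stood above the other LbaCas12a embryos at sites 6 to 9 (12.2%, 12.0%, 12.3% and 12.3%), and 11.0% of its reads held 1 deletion of 178 bp from site 3 to site 9. LbaCas12a replicate 7 stood apart at sites 10 and 11 (4.05% and 3.33%), with a deletion of 172 bp from site 5 to site 11 in 2.76% of reads, and in deletion 9D+56 (27.8%). LbaCas12a replicate 3 stood apart at sites 14 and 15 (0.661% and 0.626%), replicate 1 in the insertion share at own sites (21.3%, others 2.95% to 8.14%), and replicate 6 in deletion 11D+54 (26.0%). LbaCas12a replicate 8 stood apart in edits at SauCas9 sites (4.96%) and in deletion 9D+116 (36.3%).

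SauCas9 replicate 1 stood above the other SauCas9 embryos at sites 11 to 13 (25.4%, 25.2% and 25.1%), and 24.0% of its reads held 1 deletion of 147 bp from site 8 to site 13. SauCas9 replicate 2 stood apart at site 1 (2.88%), with a deletion of 206 bp from site 1 to site 7 in 2.69% of reads. SauCas9 replicate 7 stood apart in edits at LbaCas12a sites (5.47%) and in deletions 5D+260 (25.4%) and 4D+206 (9.98%). SauCas9 replicate 4 stood apart in edits at SpyCas9 sites (2.73%), replicate 6 in deletion 1D+205 (9.43%) and replicate 5 in deletion 6D+321 (6.42%).

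SpyCas9 sites were edited in more reads in triple than in SpyCas9 embryos. Deletions reaching in from other nucleases' sites cannot be the whole cause, since edits confined to SpyCas9 sites still differed by 41.5 percentage points (adjusted p = 4.23e-06, exact permutation test, 35 against 7 embryos). Preferred amplification of barcodes shortened at SpyCas9 sites cannot be the whole cause either. Among reads without a deletion of 20 bp or more at SpyCas9 sites, 34.7% ± 13.1 in triple and 8.26% ± 2.07 in SpyCas9 embryos had a SpyCas9-site edit. This is a difference of 26.4 percentage points (exact rank-sum permutation p = 7.41e-08, n = 35 and 7). Reads shortened at the other nucleases' sites stayed in, so their preferred amplification was not excluded. With 0 SpyCas9 embryos in the second library set, library set and any effect of the other 2 nucleases cannot be told apart.

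Edits at other nucleases' sites were above the unedited level for LbaCas12a at SauCas9 sites, SauCas9 at LbaCas12a sites, SpyCas9 at SauCas9 sites and SpyCas9 at LbaCas12a sites; the values here are for the first 3, in this order. An excess only from libraries without edits at the embryo's own sites was computed first. Reads with such edits would then lack an own-site edit in 24.0%, 47.3% and 63.9%, against 12.5%, 6.76% and 50.6% observed (exact sign-flip p = 0.00781, 0.00781 and 0.0156, n = 8, 8 and 7). The computation assumes that background calls fall evenly on reads. Of all reads 14.3%, 16.8% and 60.8% lacked an own-site edit, so the observed means lay below even that background. The assumption may not hold, so this cause was not excluded. An excess only from triple libraries would give an edit at the third nuclease's sites in 19.7%, 38.5% and 14.9%, against 9.58%, 9.19% and 9.66% observed (exact sign-flip p = 0.00781, 0.00781 and 0.0312). Unedited embryos had 12.0%, 14.8% and 9.06%, so LbaCas12a and SauCas9 embryos lay below the background here too. Only for SpyCas9 embryos do the values argue against triple libraries as the whole cause. A mixture of both was not tested. Within the first library set and without substitution calls the differences were 0.0990, 0.855 and 0.104 percentage points (exact p = 1, 0.0360 and 0.0549; adjusted p = 1, 0.108 and 0.110, ranges over their alternatives 0.000357 to 1, 3.75e-05 to 0.108 and 0.00116 to 0.920), and the folds were 1.12 (bootstrap interval 0.871 to 1.495), 2.82 (1.27 to 5.73) and 1.13 (1.00 to 1.26), against 1.13, 2.03 and 1.08 with substitution calls. For SauCas9 at LbaCas12a sites the call ended only after adjustment over 6 comparisons. The interval there stayed above 1 without any 1 embryo (lower end at least 1.10, exact p up to 0.0712). The criterion first used, an adjusted p below 0.05, was missed, and the one on the interval was set later with the values known. Whether base-substitution errors are the whole cause there therefore stays open. For the remaining comparisons they and other causes cannot be told apart, since the intervals held the folds with substitution calls. Counting only edits that touch a single site, with substitution calls, the differences within the first library set were 0.409, 0.216 and 0.237 percentage points (exact rank-sum p = 0.0206, 0.114 and 0.0418). Cutting of these sites by the nuclease of the group stays open as the biological explanation and was not tested.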

How the results depend on the processing

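Tests chosen only after the results were seen are those without substitution calls, within a library set, both together, with agreeing unedited embryos counted once, with confined edits, with edits in at least 50% of embryos, and leaving out 1 embryo; the 100 splits below were also chosen then. Of 1129 values under alternatives other than leaving out 1 embryo, 1015 kept direction and call or, for counts of sites or edits, stayed within a set factor of the main count: 32 of 32 for edited reads, 24 of 24 between edited groups, 19 of 21 for triple against single nuclease, 565 of 612 for sites, 36 of 54 at other nucleases' sites, 62 of 70 for alleles, 29 of 30 for multi-site deletions, 22 of 30 for type and size, and 226 of 256 for recurrent edits. By that tolerance a fall from 5913 to 4153 edits higher in triple embryos, with the rank-sum test, was scored as kept. All 24 named edits kept their call under all 8 alternatives for edits. Keeping undetermined calls in the denominator was not run, since there were 0. The causes of the changes below were not tested. Depth limits rare alleles: 3 reads were the floor.

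Without alleles of fewer than 5 reads, LbaCas12a embryos were below unedited at 2 sites instead of 4; at other nucleases' sites, LbaCas12a at SauCas9 sites differed by 0.205 percentage points and at SpyCas9 sites by -0.0319, both no longer passing, and SauCas9 at SpyCas9 sites by 0.294, reversed and passing; triple minus SauCas9 at SauCas9 sites was 0.377 (reversed, not passing). Without alleles under 0.1%, LbaCas12a embryos were below at 0 sites and SpyCas9 embryos above at 5 instead of 11, with -0.0112 at each of sites 1 to 5 (reversed); LbaCas12a at SauCas9 sites gave 0.305, at SpyCas9 sites 0.0209 (reversed), SauCas9 at SpyCas9 sites 0.224 (reversed), SpyCas9 at LbaCas12a sites -0.0112 (reversed) and at SauCas9 sites 0.0158, none passing. Without substitution calls, LbaCas12a at SauCas9 sites gave 0.181, SpyCas9 at LbaCas12a sites 0.114 and the insertion share of LbaCas12a against SpyCas9 -1.97, none passing; without edits of 1 bp the last was -0.598 and over all edits -1.57. SauCas9 at SpyCas9 sites then gave 0.0978 without substitution calls and 0.147 within the library set as well, and the deletion length of LbaCas12a against SauCas9 was -1.38 bp without edits of 1 bp and -0.375 over all edits, all reversed and not passing. Within the library set SpyCas9 at site 1 gave -0.00640 (reversed, not passing) and at LbaCas12a sites 0.212, with 0.290 with agreeing unedited embryos counted once, none passing. Within the library set and without substitution calls, LbaCas12a at SauCas9 sites gave 0.0990, SauCas9 at LbaCas12a sites 0.855, SpyCas9 at LbaCas12a sites 0.0109 and at SauCas9 sites 0.104, none passing.

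With single-site edits only, SauCas9 embryos were above at 6 sites instead of 13 and below at 4, with -0.0126, -0.0948, -0.0436, -0.150 and -0.0955 at sites 11 to 15; LbaCas12a gave -0.0425 at site 10 (reversed, not passing) and -0.125 at site 11, and SpyCas9 -0.0316 at site 10. Without rarefaction LbaCas12a had 2720 more alleles than SauCas9 (reversed), and SauCas9 1313 more than SpyCas9 (not passing). With alleles of at least 0.1%, triple minus LbaCas12a was -58.05, triple minus SauCas9 -46.05 and LbaCas12a minus SauCas9 12 (reversed, not passing). By the effective number, LbaCas12a, SauCas9 and SpyCas9 minus unedited were -1750.3, -1590.1 and -1982. With each allele once, the multi-site share of LbaCas12a against SpyCas9 was -17.5 (not passing) and the deletion length of LbaCas12a against SauCas9 4 bp (passing). Leaving out 1 embryo gave -0.145 (without LbaCas12a replicate 7) to 0.258 for LbaCas12a at site 11, -0.350 to -0.180 for SauCas9 at SpyCas9 sites and -3.94 to -1.33 for the insertion share of LbaCas12a against SpyCas9; the report names the embryos. Directions also changed, with no call, in -0.0357 to 0.0512 for SauCas9 at site 15, -3.68 to 1.13 for triple minus SauCas9 at SauCas9 sites and -0.732 to 1.55 bp for the deletion length of LbaCas12a against SauCas9.

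Edits called, in the order LbaCas12a, SauCas9, SpyCas9 and triple, with 572, 587, 431 and 5913 higher and 7, 6, 0 and 4 lower in the main test: TMM scaling gave 56, 46, 46 and 70 lower; no filter 3013, 4588, 2754 and 21602 higher and 52, 93, 52 and 626 lower; at least 50 reads 293, 195, 94 and 2033 higher, and 0 lower for LbaCas12a, SauCas9 and triple. For LbaCas12a the same library set gave 3 lower, DESeq2 11, edits in at least 50% of embryos 4 and the rank-sum test 20; for SauCas9 edits in at least 50% of embryos gave 1 lower. For triple embryos the same library set gave 0 lower, DESeq2 1, and edits in at least 50% of embryos 1100 higher and 0 lower.

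Whether replicate numbers pair embryos was not settled. Over 82 same-numbered pairs the median correlation of site profiles was 0.0860, with 39 over 0.1 and 15 best with their own number. It was highest between LbaCas12a and SpyCas9 (0.753, 6 of 7 over 0.1, 4 of 7 best with their own number, lowest -0.0350) and next between unedited and triple embryos (0.455, 9 of 14 over 0.1, 3 best); in no pair of groups were all over 0.1. With the number as a block, triple minus SauCas9 at SauCas9 sites was 5.54 (reversed, not passing), the insertion share differed by -9.66 between LbaCas12a and SauCas9 and by -1.53 between LbaCas12a and SpyCas9, neither passing, and edgeR called 1 edit lower for SpyCas9 and 7 for triple.

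In 100 splits of the embryos of each comparison into groups of the same sizes, the real one included, edgeR called most edits in the real split: 579 with LbaCas12a, 593 with SauCas9, 431 with SpyCas9 and 5917 in triple embryos, against 569, 573, 377 and 1193 in the highest of the others. Only the real split of 100 gave as many, but 100 splits cannot exclude chance. Every edited embryo lay above every unedited embryo in edited reads, so this outcome was largely set in advance. The splits do not show which single calls are right. With LbaCas12a and SauCas9 the highest of the others came close, while their median was 0 calls, as with SpyCas9. In the triple comparison the splits gave a median of 591 calls. On simulated counts there, with 200 of 5985 edits changed, 229 of 359 edgeR calls were wrong. Whether the embryos hold a structure of their own was not tested.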

Other observations

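All tests in this part were chosen only after the results were seen. Deletions over several sites mostly ran from cut to cut with SpyCas9. Taking the median midpoint of single-site deletions as the cut of each site, both ends lay within 5 bp of such a midpoint in 83.6% ± 2.10 of multi-site deletions with SpyCas9 (n = 7), 58.0% ± 21.4 with SauCas9 (n = 8) and 16.6% ± 18.0 with LbaCas12a (n = 8). Ends placed evenly over the barcode would give 22.8%, 16.5% and 15.8%. The window is narrow for LbaCas12a: its single-site deletion 17D+50 runs from 50 to 66, with both ends over 5 bp from the midpoint of 60. Its low share therefore does not show that its deletions start away from its cuts. In triple embryos the shares were 78.9% ± 2.44 at SpyCas9 sites, 54.3% ± 16.2 at SauCas9 sites and 23.2% ± 18.8 at LbaCas12a sites (n = 35).

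By reads, the edited alleles of SpyCas9 embryos overlapped more with each other than those of LbaCas12a embryos did. The overlap of 2 embryos is the sum, over shared alleles, of the smaller of their 2 shares of edited reads, so frequent alleles weigh most. Within a group it ranged from 44.6% to 60.4% with SpyCas9, from 1.91% to 22.9% with SauCas9, from 0.0855% to 13.1% with LbaCas12a and from 0.00101% to 12.9% in triple embryos. Unedited embryos gave 9.5% to 18.7%, with a median of 14.1%. At the sites of 1 nuclease alone, the median overlap between triple embryos was 47.5% for SpyCas9, 13.1% for SauCas9 and 2.23% for LbaCas12a. The most frequent edited allele took 8.28% ± 5.96 of all reads with SpyCas9, 9.74% ± 9.74 with SauCas9, 9.85% ± 7.94 with LbaCas12a and 2.34% ± 2.46 in triple embryos. Edited reads were 41.4%, 83.5%, 86.3% and 99.8% of all reads in that order. As a share of edited reads, the most frequent edited allele had its highest mean with SpyCas9, which was not tested.

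A hypothesis is that SpyCas9 edits arose in many more separate events per embryo than LbaCas12a edits, since an edit made in few cells early varies in its final share more than one made in many cells. The spread of edit shares between triple embryos (n = 35) corresponded to a median effective number of 749 events for SpyCas9 sites (bootstrap interval 584 to 1199), 104 for SauCas9 sites (31.5 to 151) and 14.4 for LbaCas12a sites (13.3 to 26.8), so the intervals of SpyCas9 and LbaCas12a lay apart. This number restates the spread that prompted the hypothesis and is no separate test of it. Convergence of deletions over several SpyCas9 sites on few outcomes cannot be the whole cause, since edits that touch 1 site gave 827 (642 to 1413) for SpyCas9 and 16.5 (15.7 to 30.1) for LbaCas12a. With edits of at least 1% or 2% mean share the numbers were 484 and 170 for SpyCas9, 38.1 and 52.4 for SauCas9 and 13.1 and 18.3 for LbaCas12a. These may reflect later or more widespread cutting by SpyCas9, as with induction by heat shock (whether only embryos with SpyCas9 were heat-shocked is not clear from the labels), but a stronger preference of SpyCas9 repair for few outcomes was not excluded, and no embryos at other stages were measured.

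Unedited embryos of the first library set had more edit calls at LbaCas12a sites (0.952% against 0.362% of reads) and SauCas9 sites (3.55% against 2.40%) than those of the second, and fewer at SpyCas9 sites (1.93%, a difference of -0.564 percentage points); each exact rank-sum permutation p was 0.000999, with n = 9 and 5 and no overlap. With agreeing embryos counted once, each was 0.0556, the smallest that 7 against 2 values can give.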
